A study of Drosophila melanogaster with 8 samples.

How the data were processed

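The data are 8 Affymetrix Drosophila Genome 2.0 arrays hybridised with total RNA of Drosophila melanogaster. They form 4 groups of 2 arrays, from 2 genotypes (wild type and the Hr39(04443) mutant) and 2 dissected organs (spermathecae, and the lower reproductive tract with the spermathecae removed). The deposited values are intensity values on a linear scale, made with MAS5 per the submitters' processing notes, which give no version. The mean of each array after dropping the lowest and highest 2% of probe sets was 150 on all 8 arrays, so the authors had scaled each array to a common trimmed mean. No detection calls, scanner settings or raw images were available. Depth does not apply to arrays, and the number of arrays limits the precision. The labels name the arrays of a group as an original and a duplicate and do not say that they came from separate animals.

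The arrays hold 18952 probe sets, of which 183 control probe sets were left out. Of the other 18769, the deposited probe annotation gave 1 gene symbol to 13647, several to 402 and none to 4720. The 13647 symbols were checked against current names through their Entrez identifiers, which matched for 13544, and 0 symbols changed. The reference annotation (release 6 of the Drosophila genome) served only for names and for the order of genes along a chromosome, so no positions are given. Values were taken to log2 after adding a pseudocount of 4, the 20th percentile of all values. A probe set was kept when its value was at or above its own array's median on both arrays of at least 1 group. This left 10113 probe sets, 8562 of them with 1 symbol, covering 7827 genes. Of the 10113, 1485 carry a suffix that marks probes shared between transcripts of several genes or families.

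Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with 1 mean per group over all 8 arrays, 4 residual degrees of freedom and 5.75 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 10113 probe sets of each comparison, with calls at an adjusted p below 0.05. The 5 comparisons were mutant against wild type in each organ, spermathecae against lower tract in each genotype, and the difference between the organs in the mutant effect (interaction). Standard errors are those of the log2 difference, and the errors of group means are standard deviations over 2 arrays. On simulated data, 100 probe sets were changed by a log2 difference of 1 and another 100 by 2. The difference of 1 was recovered for 44% in the spermathecae and 52% in the lower tract, and that of 2 for 87% and 79%. The simulations gave 13 and 15 false calls among 10113 probe sets. Right calls for differences of 1 and 2 numbered 44 and 87 in the spermathecae and 52 and 79 in the lower tract. False calls were thus a larger share of all calls than the threshold of 0.05 implies.

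Before the data were examined, 28 gene lists were fixed from general knowledge. They cover nuclear receptors, ecdysteroid metabolism, reproductive tract patterning factors, serine proteases, spermathecal proteases, serpins, antimicrobial peptides, immune recognition, antioxidant enzymes, glutathione S-transferases, cytochromes P450, odorant-binding proteins, the secretory pathway of the endoplasmic reticulum (ER), glycan and mucin genes, cuticle and chitin genes, heat shock proteins, ribosomal proteins and oxidative phosphorylation. Further lists mark other tissues that a dissection can hold: muscle, neurons, octopamine and neuropeptide receptors, germline, eggshell, fat body, hemocytes, male accessory gland, sperm and testis, and gut with Malpighian tubules. Of the 1015 probe sets in any list, 45 are in more than 1. Lists with at least 5 tested probe sets (27 of 28) were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. In a simulation with 1 shifted list, camera called 1 of 27 lists. The simulated probe sets varied independently, so this does not show how the preset performs where members are correlated. The estimated correlation was 0.697 for the spermathecal proteases.

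Genes to name were chosen by a rule fixed before the data were examined. It takes, in each of the 3 main comparisons, the 10 largest rises and 10 largest falls among called probe sets with 1 symbol and no overlap between the arrays of the compared groups, with 1 probe set per gene. It adds Hr39 and its paralog ftz-f1 always, up to 4 called members of each list by adjusted p, and the 5 smallest p of the interaction.

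Alternatives fixed in advance were quantile normalization, centring each array on its median, no pseudocount, a pseudocount of 20, no filter, a stricter filter at the 75th percentile, no variance trend, a robust variance, fitting only the 4 arrays compared, a replicate block, a call at an adjusted p below 0.01, an added 2-fold minimum (both fixed only for counts of genes), and leaving out each array in turn. Alternatives chosen after seeing the data were the removal of 198 probe sets near the brightest spike-in signal, fits of each organ alone for the changes shared by both organs, camera with a variance trend, the counts without the arrays that carried germline transcripts or a high Act5C 3'/5' ratio, all other alternatives for the changes shared by both organs, all alternatives for the calls among bright spermathecal proteases, both call thresholds for the named genes, other pseudocounts for the interaction of named genes, and each array left out for the tract-enriched probe sets. Where an array is left out, its group has 1 array, which is assumed to vary like the other groups. The expected counts for overlapping calls came from independence. A set of 50 simulations with no effect shows only how many overlapping calls arise where no probe set differs between the genotypes. No group is large enough for the test of single outlying samples or for other splits of the samples, and these were left out.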

Results

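RNA was measured on 8 microarrays in 2 organs of 4-day-old mated female fruit flies. The spermathecae are the paired glands that store and nourish sperm, and the lower tract is the rest of the lower reproductive tract. Each organ came from wild-type females and from females carrying the Hr39(04443) mutation, with 2 arrays per group. The labels name no wild-type strain. Effects of the mutation below are differences between the genotypes, which may also differ in strain background, and this was not tested. They are differences between whole dissected organs, and levels within single cell types were not measured. Hr39 encodes a nuclear receptor related to mammalian SF-1, and the series asks what it contributes to the development and function of the female tract. Values are array signals (MAS5, linear scale), differences are on the log2 scale with their standard error (SE), and n = 2 arrays per group throughout. The labels do not say that the arrays came from separate animals, so the adjusted p-values measure only the spread between these samples, which may be technical.

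Arrays of the same group correlated across probe sets with r from 0.963 to 0.979, and the best correlation with an array of another group was 0.946. A pair of arrays stood apart in other measures. Wild-type lower tract replicate 1 carried germline transcripts, with a signal of 555.6 for osk, which specifies germ cells, against 20.8 on replicate 2, and of 1134 for CycB against 88.2. On wild-type spermathecae replicate 1 the 3' to 5' signal ratio of the Act5C control, which rises with RNA degradation, was 24.9, against 3.56 to 4.80 on the other 7 arrays. The Gapdh ratio there was 5.87 against 2.46 to 4.05, while the eIF4A ratio of 3.17 lay within the 2.75 to 3.35 of the others.

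Hr39 itself was 9.18-fold higher in wild-type spermathecae than in wild-type lower tract on probe set 1630002_s_at (log2 difference 3.20, SE 0.177, adjusted p = 4.44e-07). On its other 3 probe sets it was 6.27-fold (1631402_s_at), 2.84-fold (1628556_s_at) and 2.63-fold (1632845_at) higher, with adjusted p of 1.81e-06, 0.00119 and 0.0324. Probe set 1632845_at lay below the array medians in the lower tract, so its fold depends on the pseudocount. In mutant spermathecae 1630002_s_at read 465 ± 17.8 (SD, n = 2) against 773 ± 67.5 in wild type, a log2 difference of -0.73 (SE 0.177, adjusted p = 0.0351). The other 3 Hr39 probe sets did not pass in the spermathecae. Probe set 1631402_s_at read 365 ± 24.7 in the mutant and 544 ± 37.3 in wild type (adjusted p = 0.0889), 1632845_at read 13.4 against 22.8 (adjusted p = 0.485), and 1628556_s_at read 185 against 194 (adjusted p = 0.941). In the lower tract none of the 4 passed in limma: 1630002_s_at read 62.5 against 80.8 (adjusted p = 0.368), 1631402_s_at 53.7 against 83.4 (adjusted p = 0.0947), 1632845_at 0.641 against 6.19 (adjusted p = 0.226) and 1628556_s_at 62.3 against 64.6 (adjusted p = 0.961). The call of a lower Hr39 transcript in mutant spermathecae therefore rests on 1 probe set of 4, although all 4 averaged lower in the mutant in both organs. Before adjustment the limma p in the spermathecae was 0.00223 (1630002_s_at), 0.00977 (1631402_s_at), 0.205 (1632845_at) and 0.85 (1628556_s_at). In the lower tract it was 0.0803, 0.00735, 0.0326 and 0.855 in the same order. It is not stated which part of the transcript the mutation alters. Probe sets 1630002_s_at, 1631402_s_at and 1628556_s_at carry the suffix that marks probes shared between transcripts of several genes or families. The adjusted p of 1630002_s_at was 0.0826 with quantile normalization, 0.0648 with median centring, 0.0515 with no filter and 0.0681 with no variance trend. It was 0.0651 without mutant lower tract replicate 1, 0.0654 without mutant lower tract replicate 2, 0.139 without mutant spermathecae replicate 1, 0.208 without mutant spermathecae replicate 2 and 0.142 without wild-type spermathecae replicate 1. The paralog ftz-f1 did not pass in either organ, with log2 differences of -0.19 and 0.07 on its 2 probe sets in the spermathecae and -0.17 and 0.33 in the lower tract.

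**Figure D1:**
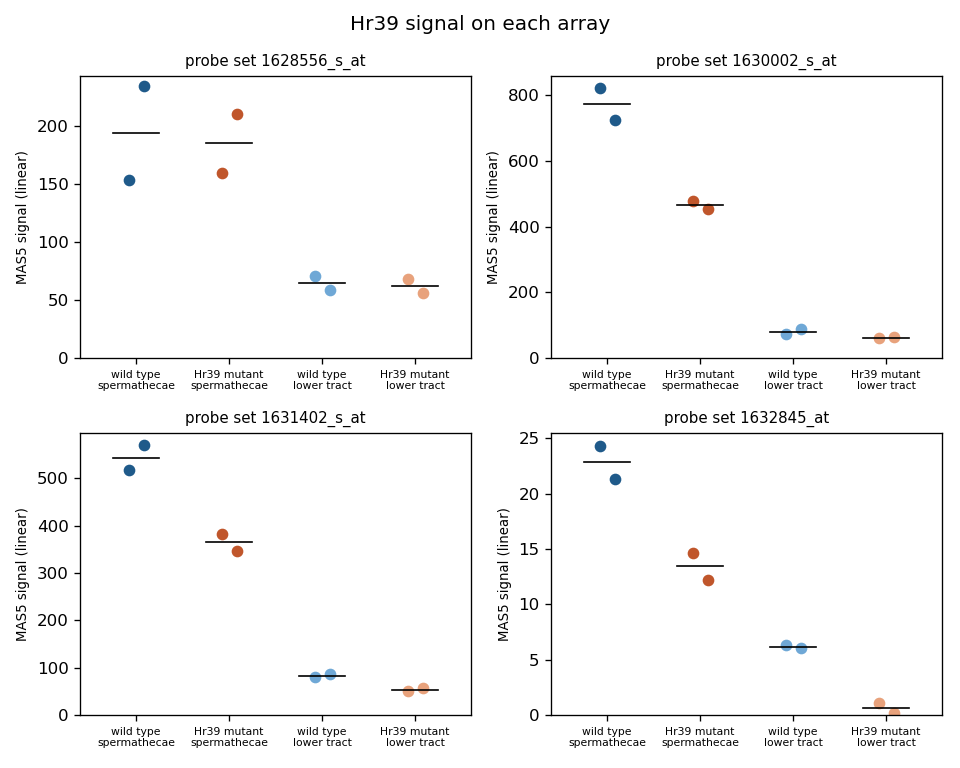
Signal (MAS5, linear axis from 0) of the 4 Hr39 probe sets on each of the 8 arrays, with bars at the group means. On probe set 1630002_s_at the mutant spermathecae average 465 and the wild-type spermathecae 773, and the lower tract arrays lie far below both.

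The comparison of the organs in wild type asks what distinguishes the spermathecae. Among serine proteases of the spermathecae, CG32277 was higher there by a fitted 9.56 (SE 0.981, adjusted p = 3.44e-05), CG32834 by 9.09, CG17234 by 8.27, and Send2 (spermathecal endopeptidase) by 8.23. These sizes are not exact, since the spermatheca signals of all 4 lie near the top of the scale and their lower tract signals varied, as for CG32834 at 75.1 ± 103. CAH8, a member of the carbonic anhydrase family, was higher by 9.12 (4234 ± 2114 against 3.15 ± 0.146, adjusted p = 4.62e-08). In the lower tract the cuticle protein gene Pcp was higher, with a log2 difference of -9.61 (2.59 ± 2.35 in spermathecae against 4987 ± 287, adjusted p = 1.25e-08). The other largest falls, SmydA-9, CG9717, CG7443, CG43394, pncr003:2L, CG7300, CG7201, Cpr65Au and cysu, ranged from -8.38 to -7.07. Of these, CG7443 and CG7300 read 10220 and 8578 in the wild-type lower tract, near the top of the scale of those arrays. Levels near background make sizes depend on the pseudocount: with none and with 20, CAH8 differed by 10.3 and 7.43, and Pcp by -11.2 and -7.79. The same limit holds for SmydA-9, CG9717, CG43394, pncr003:2L, CG7201, cysu, CG30271 and CG34288, whose signals in the organ with less signal were below the array medians. The remaining large rises, CG30271, CG9897, CG34288, CG42284 and CG17239, ranged from 6.93 to 8.04, and CG9897 and CG17239 are proteases near the top of the scale.

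The groups of genes differed between the organs in the same comparison. Of 11 spermathecal protease probe sets 9 were higher in spermathecae and 1, CG13318, was lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.000269, adjusted p = 0.515 with an estimated correlation). The signals of 8 of these lay between 12140 and 22890, close to the brightest spike-in control of the spermathecal arrays. Their mean log2 signal also differed between replicate arrays of the lower tract, at 7.49 and 4.91 in wild type and at 8.37 and 6.70 in the mutant. Genes of the ER secretory pathway were higher in spermathecae for 32 of 37 probe sets (33 adjusted over the list alone, camera adjusted p = 3.49e-14, adjusted p = 0.139 with an estimated correlation), among them TRAM at 3.40 and the chaperone Gp93 at 2.96. Ribosomal protein genes were higher for 34 of 43 probe sets and lower for 1 (35 and 1 adjusted over the list alone, camera adjusted p = 1.47e-05, adjusted p = 0.523 with an estimated correlation), with RpS21 at 1.22. With quantile normalization the camera adjusted p of the ribosomal list was 0.0747, and without near-saturated probe sets 0.121. Muscle genes were lower in spermathecae for 41 of 42 probe sets (41 adjusted over the list alone, camera adjusted p = 7.1e-21, adjusted p = 0.139 with an estimated correlation), as for Act87E at -6.71 and Tm2, a tropomyosin, at -3.65. Cuticle and chitin genes were lower for 29 of 64 and higher for 10 (29 and 11 adjusted over the list alone, camera adjusted p = 0.00223, adjusted p = 0.162 with an estimated correlation, camera adjusted p = 0.0743 with no filter), with Cpr47Ef at -6.13.

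Further groups were lower in wild-type spermathecae than in the lower tract. Hemocyte genes were lower for 17 of 21 probe sets, such as Pxn (peroxidasin) at -5.58, and higher for 1, the GATA factor srp at 3.96 (17 and 1 adjusted over the list alone, camera adjusted p = 2.45e-06, adjusted p = 0.139 with an estimated correlation). Immune recognition genes were lower for 19 of 33 and higher for 3 (20 and 4 adjusted over the list alone, camera adjusted p = 0.00223, adjusted p = 0.139 with an estimated correlation), with PGRP-LB at -2.97 and PGRP-SC2 at 3.43. Odorant-binding protein genes were lower for 12 of 21 and higher for 3 (13 and 3 adjusted over the list alone, camera adjusted p = 0.00401, adjusted p = 0.465 with an estimated correlation), and Obp83cd was one of the 3, at 5.58. Cytochrome P450 genes were lower for 31 of 62 and higher for 11 (32 and 12 adjusted over the list alone, camera adjusted p = 0.00602, adjusted p = 0.139 with an estimated correlation, camera adjusted p = 0.153 with the stricter filter), with Cyp4d21 at -4.97 and Cyp305a1 at 6.26. Oxidative phosphorylation genes were lower for 36 of 67 and higher for 2 (39 and 2 adjusted over the list alone, camera adjusted p = 1.47e-05, adjusted p = 0.497 with an estimated correlation), with ATPsynC at -1.53. Fat body genes were lower for 10 of 16 and higher for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.0184, adjusted p = 0.583 with an estimated correlation), with Lsd-1, a lipid droplet protein, at -2.21. Without wild-type spermathecae replicate 2 the camera adjusted p of the fat body list was 0.215.

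In all, 4418 of 10113 probe sets differed between the wild-type organs, 2243 higher and 2175 lower in spermathecae (limma). The count was 3912 without wild-type lower tract replicate 1 and 3895 without wild-type spermathecae replicate 1. In the mutant 4670 probe sets differed, 2500 higher and 2170 lower in spermathecae. Of the 4418 wild-type differences, 3365 (76.2%) were called in the same direction in the mutant and 66 in the opposite direction, and both comparisons share no array. Median centring moved the median difference of all probe sets from 0.07 to 0.24, a shift of 0.17, and quantile normalization moved it by 0.11, so the listed changes are relative to such a shift.

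**Figure D2:**
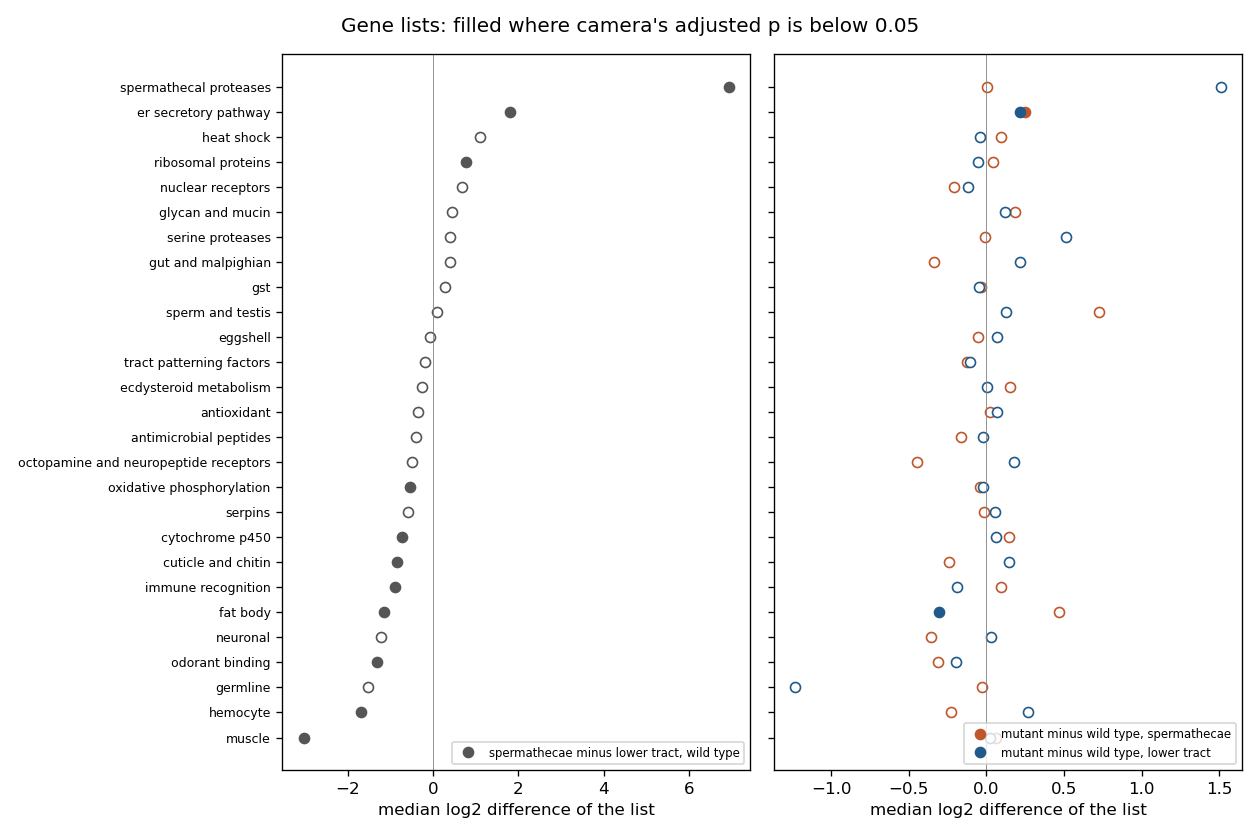
Median log2 difference of each gene list (horizontal axis, log2) for spermathecae minus lower tract in wild type (left) and mutant minus wild type in each organ (right), filled where the camera adjusted p is below 0.05. Filled points number 11 on the left, 1 for the mutant spermathecae and 2 for the mutant lower tract.

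The comparison of mutant with wild-type spermathecae asks which transcripts of that organ differ when Hr39 is mutated. NLaz, which encodes a lipocalin, fell from 2280 ± 120 to 24.4 ± 4.37, a log2 difference of -6.34 (SE 0.159, adjusted p = 4.08e-08). GlcAT-P, a glucuronyltransferase, fell from 1437 ± 268 to 46.9 ± 7.36 (log2 -4.82, SE 0.236, adjusted p = 3.67e-06). Papss, which makes the sulfate donor for sulfation, fell from 3999 ± 320 to 158 ± 75 (log2 -4.70, SE 0.27, adjusted p = 8.51e-06). The receptor tyrosine kinase gene drl fell by 5.12 and the cuticle protein gene Cpr62Bb by 4.38, and the remaining large falls, Rnf11, CG10211, Cyp4p2, GstE1 and lncRNA:CR32027, ranged from -5.51 to -4.19. The largest fitted rise was that of CG11892, from 7.41 ± 9.27 to 1028 ± 16.0 (log2 6.79, SE 0.47, adjusted p = 2.09e-05). Cyp6a17, a cytochrome P450, rose by 5.67 and beat-VII, of the beaten path family of immunoglobulin proteins, by 5.60, while CG42324, CG18088, CG34279, tobi, CG3397, CG6429 and alpha-Est5 rose by 4.32 to 5.70. Where the level of either genotype is near background, the size depends on the pseudocount: with none and with 20, Cyp4p2 differed by -5.50 and -3.40, lncRNA:CR32027 by -4.82 and -3.02, CG10211 by -6.43 and -4.17, and Rnf11 by -5.91 and -4.56. Among the rises, CG11892 was higher by 8.10 and 5.30, beat-VII by 7.47 and 3.72, and Cyp6a17 by 7.03 and 4.03.

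By group, the ER secretory pathway was the list called by camera in mutant spermathecae (median 0.25, adjusted p = 0.00559, adjusted p = 0.703 with an estimated correlation), with 2 of 37 probe sets higher and 2 adjusted over the list alone. Cnx99A, a calnexin, rose by 0.97 (adjusted p = 0.00224), and CaBP1, a disulfide isomerase, had a log2 difference of 0.68 (adjusted p = 0.0245). The CaBP1 call was lost without mutant lower tract replicate 1 (0.0554), mutant spermathecae replicate 1 (0.115), wild-type spermathecae replicate 1 (0.097), mutant lower tract replicate 2 (0.0557) and mutant spermathecae replicate 2 (0.152), with no variance trend (0.0863) and in a fit of the 4 arrays compared (0.0624). The camera adjusted p of the list was 0.222 without wild-type spermathecae replicate 2 and 0.0528 without mutant spermathecae replicate 2. Cytochrome P450 genes rose for 9 of 62 probe sets and fell for 8 (14 and 11 adjusted over the list alone), with Cyp6w1 at 2.64 and Cyp6a14 at -3.93. Odorant-binding protein genes rose for 1 of 21 and fell for 4 (2 and 5 adjusted over the list alone), the 4 being Obp57c at -2.32, Obp8a at -2.94, Obp57a at -1.54 and Obp57b at -1.41. Glutathione S-transferase genes rose for 3 of 29 and fell for 3 (6 and 4 adjusted over the list alone), with GstE1 at -4.21 and GstE11 at 1.91. Cuticle and chitin genes rose for 1 of 64, Cpr66Cb at 3.37, and fell for 6 (1 and 7 adjusted over the list alone). Muscle genes rose for 6 of 42 and fell for 1 (7 and 2 adjusted over the list alone), with Strn-Mlck at 1.45. The muscle gene Mf had probe sets called in opposite directions, with 2.81 on one, and so had Atat, CG14642, CG43078 and teq.

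The bright proteases of the spermathecae showed no called difference: none of the 8 with signals from 12140 to 22890 passed in limma (median log2 difference -0.00, smallest adjusted p = 0.973). Their median SE of 0.977 reflects the lower tract arrays, where the replicates had a median SD of 2.02 in log2 signal, against 0.319 in the spermathecae. A fit of the 4 spermatheca arrays alone, chosen after seeing the data, gave a median SE of 0.262 and also called 0 of the 8 (smallest adjusted p = 0.884). Near the top of the scale this does not show that the transcripts are equal. Over the whole list of 11 spermathecal proteases, 1 rose and 1 fell (1 and 1 adjusted over the list alone). Among serine proteases 2 of 23 rose and 3 fell (3 and 3 adjusted over the list alone), with ea, the protease easter, at -1.53. That list also holds SP1029, which is an aminopeptidase. Glycan and mucin genes rose for 4 of 21 and fell for 1, Papss (4 and 1 adjusted over the list alone). Serpins rose for 1 of 18 and fell for 2 (1 and 2 adjusted over the list alone), with Spn28Dc at -1.39. Immune recognition genes rose for 3 of 33 and fell for 2 (4 and 3 adjusted over the list alone), with NimB2 at -1.49 and GNBP2 at 1.25. Their median was 0.09 and their mean 0.04 while camera gave the direction down (adjusted p = 0.805).

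In each of the other lists 0 to 3 probe sets were called in mutant spermathecae. Nuclear receptors had 1 of 17 higher and 2 lower (2 and 3 adjusted over the list alone), patterning factors 1 of 18 higher and 1 lower (1 and 2 adjusted over the list alone), and ecdysteroid metabolism 1 of 8 higher, the sterol carrier Npc2a at 1.36 (1 adjusted over the list alone). Fat body genes had 3 of 16 higher and 0 lower (3 and 0 adjusted over the list alone, median 0.47, camera adjusted p = 0.105). Their mean log2 signal was 9.49 and 8.75 on wild-type spermathecae replicates 1 and 2, against 9.88 and 9.77 in the mutant, so the size of the shift depends on wild-type replicate 2. Hemocyte genes had 0 of 21 higher and 2 lower (0 and 2 adjusted over the list alone). Antimicrobial peptides had 1 of 15 higher, antioxidant enzymes 1 of 18 higher, and heat shock proteins 1 of 6 higher, each with 1 adjusted over the list alone. Oxidative phosphorylation had 2 of 67 higher (1 adjusted over the list alone), with ND-13B at 0.97, and its median of -0.04 had the opposite sign to its mean of 0.03 and to camera's direction up (adjusted p = 0.885). Ribosomal proteins had 1 of 43 higher (0 adjusted over the list alone), and gut with Malpighian tubules 1 of 7 higher and 1 lower (1 and 1 adjusted over the list alone). Neuronal genes had 1 of 12 lower, octopamine and neuropeptide receptors 1 of 7 lower, rk (the bursicon receptor) at -1.83, and germline genes 1 of 13 lower, egl at -1.52, each with 1 adjusted over the list alone. Eggshell genes had 0 of 7 called (1 lower adjusted over the list alone). Sperm and testis genes had 0 of 6 called (0 adjusted over the list alone), with a median of 0.72 and a camera adjusted p of 0.284, and the male accessory gland list, with 3 probe sets, was too small for camera and had 0 called (0 adjusted over the list alone).

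In mutant spermathecae 802 of 10113 probe sets differed from wild type, 409 higher and 393 lower. The count was 534 without wild-type spermathecae replicate 1, the array with the high Act5C ratio, and 448 of the 802 stayed called in the same direction. It was 796 without wild-type lower tract replicate 1, 413 without mutant spermathecae replicate 1 and 313 without mutant spermathecae replicate 2.

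**Figure D3:**
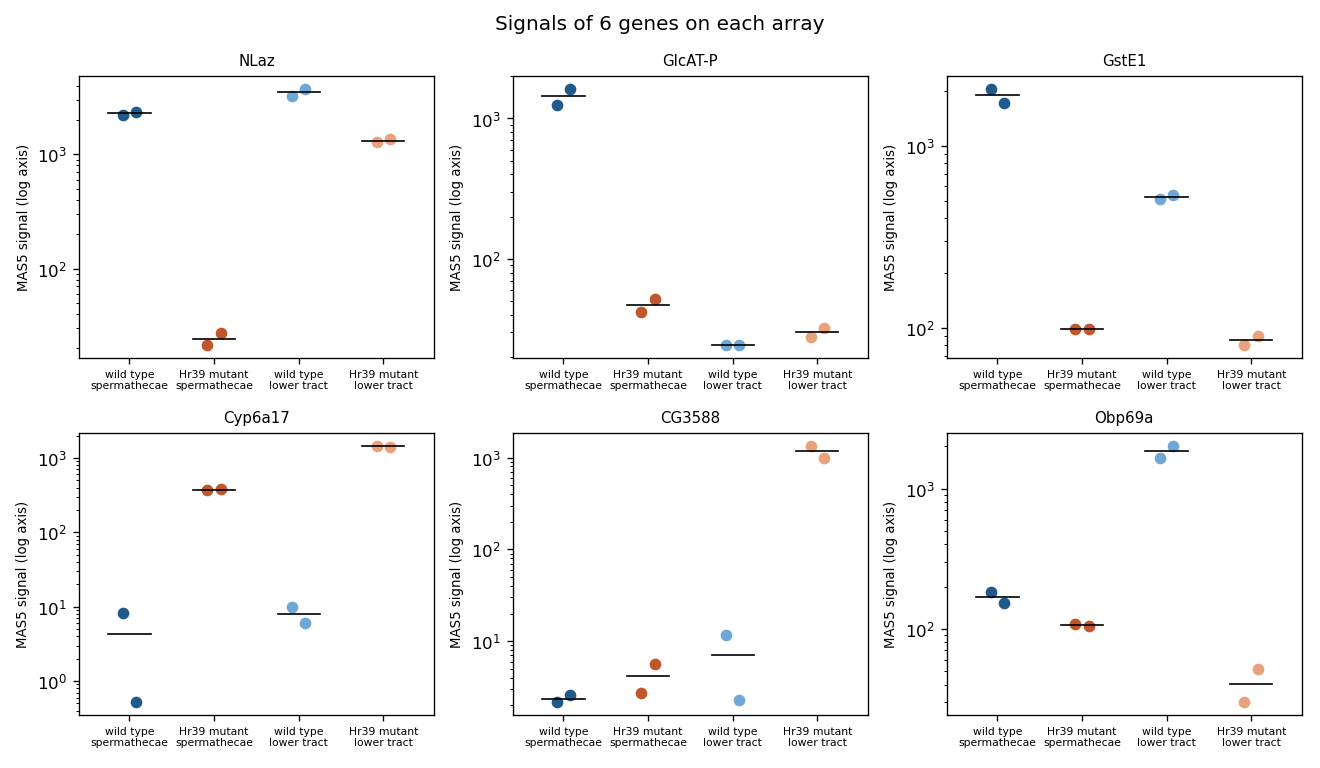
Signal (MAS5, log axis) of NLaz, GlcAT-P, GstE1, Cyp6a17, CG3588 and Obp69a on each of the 8 arrays, with bars at the group means. NLaz averages 2280 in wild-type and 24.4 in mutant spermathecae, and 3499 and 1320 in the lower tract.

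The comparison of mutant with wild-type lower tract asks the same question of the rest of the tract. Cyp6a17 rose from 7.89 ± 2.68 to 1436 ± 26.1 (log2 6.94, SE 0.401, adjusted p = 1.35e-05), and CG3588 from 7.01 ± 6.69 to 1167 ± 249 (log2 6.86, SE 0.467, adjusted p = 3.18e-05). The odorant-binding protein genes Obp83g and Obp83cd rose by 5.91 and 3.89, and the fatty acid elongase gene Elo68alpha by 5.76. Obp69a, another odorant-binding protein gene, fell from 1840 ± 250 to 40.6 ± 15.2, a 42.4-fold change (SE of the log2 difference 0.243, adjusted p = 5.68e-06), and teq, a serine protease gene, fell by 5.32. The remaining large falls, Elovl7, CG5399, cas, CG30371, esn, CG13931, Ugt35C1 and CG13215, ranged from -4.96 to -3.76. CG14419, beat-VII, Cyp4d21, CG11892 and CG13794 rose by 4.24 to 5.91. Cyp6a17 was higher by 7.55 with no pseudocount and by 5.71 with a pseudocount of 20, and CG3588 by 7.80 and 5.46. The wild-type lower tract signals of Obp83g, CG14419, Elo68alpha and beat-VII also lay below the array medians, so their sizes likewise depend on the pseudocount. Several falls ended near background, so their sizes and order depend on it too: with none and with 20, teq differed by -5.92 and -4.13, Elovl7 by -5.39 and -3.98, cas by -5.18 and -2.56, CG13931 by -5.90 and -2.13, Ugt35C1 by -4.78 and -2.51, and CG13215 by -4.89 and -2.30.

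By group, odorant-binding protein genes rose for 3 of 21 probe sets and fell for 6 in the mutant lower tract (5 and 7 adjusted over the list alone). Cytochrome P450 genes rose for 6 of 62 and fell for 8 (12 and 11 adjusted over the list alone), with Cyp4d21 at 4.71 and Cyp4p1 at -3.03. Glutathione S-transferase genes rose for 1 of 29, GstE11 at 1.96, and fell for 2 (1 and 3 adjusted over the list alone), with GstE1 at -2.57. The ER secretory pathway was called by camera (median 0.22, adjusted p = 0.00149, adjusted p = 0.814 with an estimated correlation), with 2 of 37 higher, Cnx99A at 0.77 and zetaCOP, a coat protein of transport vesicles, at 1.36 (2 adjusted over the list alone). Both of these single calls were lost without mutant lower tract replicate 1 (adjusted p 0.129 and 0.0899), wild-type lower tract replicate 1 (0.0643 and 0.0585) and mutant lower tract replicate 2 (0.0699 and 0.11), and that of Cnx99A also with no variance trend (0.0542). Fat body genes were also called, as lower (median -0.31, camera adjusted p = 0.0244, adjusted p = 0.814 with an estimated correlation), with 5 of 16 lower and 0 higher (7 and 1 adjusted over the list alone). Apoltp, a lipid transfer particle protein, fell by 2.33 (adjusted p = 0.000317). The camera adjusted p of the fat body list was 0.171 without mutant lower tract replicate 1, 0.0829 without wild-type lower tract replicate 2 and 0.0796 without near-saturated probe sets, and the fry adjusted p was 0.314.

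Germline genes had a median of -1.23 in the mutant lower tract, with 0 of 13 called (0 adjusted over the list alone, camera adjusted p = 0.0795), and the wild-type array with germline transcripts enters this median. Spermathecal proteases had a median of 1.51 with 0 of 11 called (0 adjusted over the list alone, camera adjusted p = 0.183). Immune recognition genes rose for 3 of 33 and fell for 4 (3 and 4 adjusted over the list alone), with NimC1, a phagocytic receptor of hemocytes, at 2.82. Hemocyte genes rose for 2 of 21 (3 adjusted over the list alone, camera adjusted p = 0.125). Serpins fell for 2 of 18 (3 lower and 3 higher adjusted over the list alone), with Spn47C at -2.34. Medians and means differed in sign for serpins (0.06 and -0.01, camera up), for patterning factors (-0.11 and 0.01, camera down), for ecdysteroid metabolism (0.00 and -0.34, camera down) and for oxidative phosphorylation (-0.02 and 0.04, camera up), and none of these lists passed camera.

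In the mutant lower tract 587 of 10113 probe sets differed from wild type, 250 higher and 337 lower. The count was 333 without wild-type lower tract replicate 1, the array with germline transcripts, and 297 of the 587 stayed called in the same direction. It was 712 without wild-type spermathecae replicate 1, 178 without mutant lower tract replicate 1 and 233 without mutant lower tract replicate 2.

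The effect of the mutation was also compared between the organs. NLaz fell by 6.34 in the spermathecae and by 1.40 in the lower tract, a difference of -4.94 (SE 0.225, interaction adjusted p = 1.28e-05). GlcAT-P differed by -5.08 (SE 0.334, adjusted p = 0.000139) and Obp69a by 4.77 (SE 0.344, adjusted p = 0.000165). GlcAT-P read 24.3 in the wild-type lower tract, just above the array medians of 22.1 and 20.2. A fall there as large as that in the spermathecae could not be measured. Elal rose by 2.49 in the spermathecae and fell by 1.67 in the lower tract (difference 4.16, SE 0.239, adjusted p = 5.75e-05), and the cadherin gene Cad87A differed by 3.57 (SE 0.257, adjusted p = 0.000165). In all 308 probe sets passed the interaction test, 178 with the higher effect in spermathecae and 130 with the lower. The count was 190 without wild-type lower tract replicate 1, 341 without wild-type spermathecae replicate 1, 116 without mutant lower tract replicate 1, 139 without mutant lower tract replicate 2, 171 without mutant spermathecae replicate 1 and 171 without mutant spermathecae replicate 2.

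Many changes were shared by both organs. Cyp6a17, CG11892, beat-VII, tobi and CG3397 rose in both, and GstE1, Cyp4p2 and Rnf11 fell in both. Of 215 probe sets called in both organs, 95 were higher in both, 101 lower in both and 19 opposite, against 10.1 and 13.1 same-direction calls under independence. The 196 same-direction calls named 158 genes. The mutant effects of the organs correlated across probe sets with r = 0.326, and genes are not independent replicates. The 196 became 82 without mutant lower tract replicate 1, 94 without mutant lower tract replicate 2, 126 without mutant spermathecae replicate 1 and 108 without mutant spermathecae replicate 2.

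**Figure D4:**
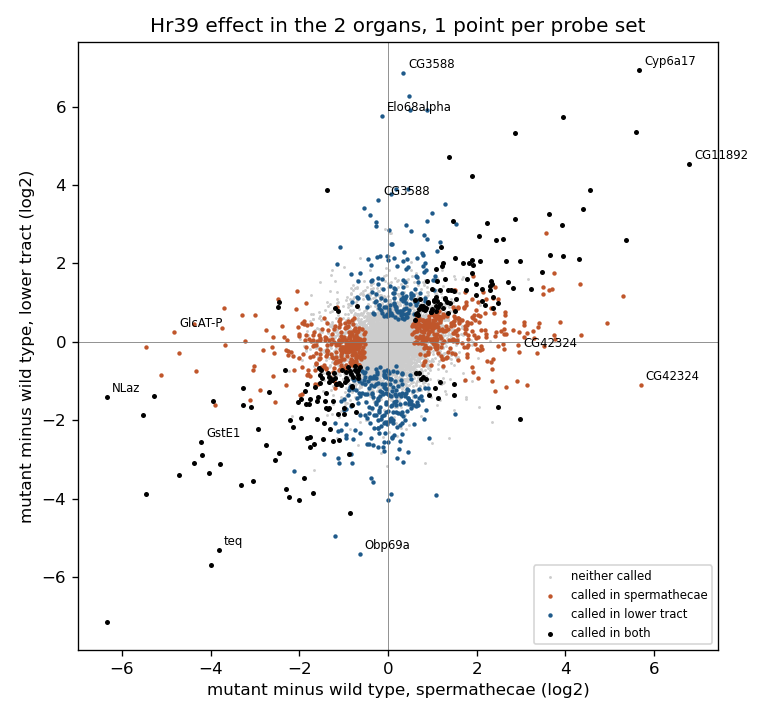
Log2 difference of mutant minus wild type in the spermathecae (horizontal axis) and the lower tract (vertical axis), 1 point per probe set, coloured by the organ in which it was called. Of the 215 called in both organs, 95 lie in the upper right and 101 in the lower left.

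The genes enriched in wild-type spermathecae were followed into the mutant. NLaz is not among them, while CG30271 and Papss are, with 2956 ± 130 and 3999 ± 320 in wild-type spermathecae against 371 ± 102 and 158 ± 75 in the mutant. Of the 2243 spermatheca-enriched probe sets, 151 (6.73%) were lower and 98 (4.37%) higher in mutant spermathecae, against 87.2 and 90.7 under independence. Simulations with no effect gave 0.14 and 0.02, but they held no mutant difference for any probe set. They therefore give no chance value for the overlap of real calls through shared arrays. Of the 2175 tract-enriched probe sets, 111 were lower and 171 higher in mutant spermathecae, against 84.5 and 88 under independence. In the mutant lower tract 174 of these 2175 (8%) were lower and 77 higher, against 72.5 and 53.8, and of the 2243 spermatheca-enriched 59 were lower and 82 higher, against 74.7 and 55.4. The same wild-type arrays enter both comparisons, so part of the excess may come from shared arrays, and the parts cannot be separated. Wild-type lower tract replicate 1, which carried germline transcripts, is a shared array for the tract-enriched set. Without it 1793 probe sets were tract-enriched, and 94 of these (5.24%) were lower and 29 higher in the mutant lower tract, against 34.6 and 24.5 under independence. Without mutant lower tract replicate 1 the counts were 70 and 12, against 23.1 and 12, and without mutant lower tract replicate 2 they were 86 and 20, against 30.8 and 15.2. These values for the tract-enriched set were chosen after seeing the data. The share of spermatheca-enriched probe sets that were lower was 3.36% without mutant spermathecae replicate 1, 3.36% without mutant spermathecae replicate 2, and 3.89% without wild-type spermathecae replicate 1. The share that were higher was 1.9%, 1.46% and 2.54% without the same arrays.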

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

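The interaction tests below were fixed before the data were examined, except under other pseudocounts. In the weighing of changes shared by both organs, the test of a shared estimate of the spread was chosen only after the result was seen, and the tests of sequence variants were chosen before.

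The mutant effect differed between the organs for 308 probe sets (limma interaction test). All values that follow are the log2 effect of the mutation in spermathecae minus that in the lower tract, and each passed that test. Among genes with the larger change in the spermathecae, the difference was 6.8 for CG42324, 4.12 for CG18088, 4.46 for CG34279, 4.17 for CG6429, 2.84 for alpha-Est5, 3.57 for Cad87A, 3.66 for Cpr66Cb, 1.94 for Cyp6w1, 2.85 for TotC and 1.39 for Strn-Mlck, all of which were higher there. It was 1.43 for Mf on a probe set that was higher there by 2.81, while another probe set of Mf was lower by 0.84. The difference was -4.94 for NLaz, -3.66 for Rnf11, -5.33 for CG10211, -4.28 for drl, -5.08 for GlcAT-P, -4.43 for Papss, -4.84 for Cpr62Bb, -1.64 for GstE1, -2.43 for Cyp6a14, -1.22 for ea, -1.48 for Spn28Dc, -1.61 for Obp57c, -1.34 for Obp57a, -1.46 for Obp57b, -2.16 for Cpr67Fb and -1.11 for Ppn, all of which were lower there.

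Among genes with the larger change in the lower tract, the difference was -6.52 for CG3588, -5.03 for Obp83g, -5.41 for CG14419, -5.9 for Elo68alpha, -3.35 for Cyp4d21, -2.35 for CG13794, -3.72 for Obp83cd, -2.31 for NimC1, -3.49 for Cht10, -1.07 for pio, -1.85 for Cpr49Ae and -1.38 for PPO1, which were higher in the mutant lower tract. It was 4.77 for Obp69a, 3.76 for Elovl7, 3.51 for CG5399, 4.03 for CG30371, 4.99 for esn, 3.94 for CG13931, 2.27 for Spn47C, 2.03 for PGRP-SC2, 1.46 for GstS1, 2.25 for TwdlT, 2.12 for Apoltp and 1.68 for apolpp, which were lower there. For Elal (4.16), which rose in mutant spermathecae and fell in the mutant lower tract, and for Lsd-1 (1.7), whose effects were 0.75 and -0.96, the directions were opposite.

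Some genes had probe sets that disagree. For beat-VII the difference was -1.78 on 1 probe set, but 0.26 on another (adjusted p = 0.884), which was higher by 5.60 in mutant spermathecae and by 5.34 in the mutant lower tract. Further probe sets did not pass for Rnf11 (-1.64, adjusted p = 0.302), Cad87A (0.68, adjusted p = 0.741), Strn-Mlck (-0.08, adjusted p = 0.964), esn (0.16, adjusted p = 0.955) and pio (-0.83 and -0.73, adjusted p = 0.708 and 0.153).

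Signals near background limit others. On every spermatheca array CG3588, CG14419, Elo68alpha, Cyp4d21, CG13931 and Cht10 lay below the array median, as did CG18088, CG34279 and alpha-Est5 on every lower tract array. A fall in that organ could thus not be measured. The difference for CG13931, which fell in the lower tract, therefore says only that the lower tract changed. The rest of these 9 genes rose in the other organ, and a rise as large was not seen in the organ with low signal. Cyp4d21 also rose in the spermathecae, by 1.36 (limma adjusted p = 0.0115). Low starting signals limit further genes. Elovl7 and esn read 18.4 and 14.3 in wild-type spermathecae, and GlcAT-P read 24.3 in the wild-type lower tract. From those levels a fall as large as that in the other organ could not be measured. Their differences therefore do not show that the fall was confined to the other organ. The sizes depend on the pseudocount, and other pseudocounts were tried on these tests only after seeing the data. With none and with 20, the difference was -7.07 and -5.35 for CG3588, -7.55 and -3.99 for Elo68alpha, 6.16 and 2.14 for CG13931, 4.96 and 3.11 for CG34279, 7.79 and 5.33 for CG42324, and -5.62 and -3.97 for Obp83g. With no pseudocount 44 of the 54 genes passed. Those that did not were CG18088 (adjusted p = 0.159), CG34279 (0.0792), alpha-Est5 (0.417), CG14419 (0.141), Cyp4d21 (0.159), Elovl7 (0.205), CG13931 (0.09), TotC (0.0655), NimC1 (0.0764) and Cht10 (0.0502). With a pseudocount of 20 only beat-VII did not pass (0.181).

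Signals near the top of the scale limit the values of 3 of these genes. CG30371 read 14810 in wild-type and 14730 in mutant spermathecae, so a change there may be hidden and its 4.03 is not exact. No fall was seen there, but the transcript level behind a signal near the ceiling is not known. A fall as large as that in the lower tract is therefore not excluded. Obp57a read 9344 and 8167 in the wild-type and mutant lower tract, and Mf read 10430 in the mutant lower tract.

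Several of the calls within an organ were lost under alternatives. In the lower tract those of Cpr49Ae were lost under 7, pio under 6, Cht10 and apolpp under 4, and PPO1, TwdlT and Lsd-1 under 3. All 7 were lost without mutant lower tract replicate 1 (adjusted p 0.192 for Cpr49Ae, 0.32 for pio, 0.111 for Cht10, 0.124 for apolpp, 0.13 for PPO1, 0.061 for TwdlT and 0.157 for Lsd-1). All 7 were also lost without mutant lower tract replicate 2 (0.204, 0.0949, 0.0968, 0.0594, 0.143, 0.109 and 0.104 in the same order). All but Cht10 were lost without wild-type lower tract replicate 1 (0.2 for Cpr49Ae, 0.123 for pio, 0.0551 for apolpp, 0.0786 for PPO1, 0.0561 for TwdlT and 0.0894 for Lsd-1). GstS1 lost its call without mutant lower tract replicate 1 (0.081) and PGRP-SC2 without mutant lower tract replicate 2 (0.0707). In the spermathecae Lsd-1 lost its call under 12 alternatives, TotC under 3, and Ppn in a fit of the 4 arrays compared (0.0503).

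By camera, 3 lists differed between the organs. The fat body list had a median difference of 0.99 (adjusted p = 0.000141, adjusted p = 0.81 with an estimated correlation) and 4 of 16 probe sets past the test. Wild-type spermathecae replicate 2, with a mean log2 signal of the list of 8.75 against 9.49 on replicate 1, enters this difference. Octopamine and neuropeptide receptors had a median difference of -0.62 (adjusted p = 0.0247, adjusted p = 0.657 with an estimated correlation) and 0 of 7 past the test. Hemocyte genes had a median difference of -0.29 (adjusted p = 0.0145, adjusted p = 0.657 with an estimated correlation) and 3 of 21 past the test. The number of lists passing was 1 without mutant lower tract replicate 1, 5 without mutant spermathecae replicate 2, and 6 without mutant lower tract replicate 2 or wild-type lower tract replicate 2.

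The changes that went the same way in both organs, 196 against 23.2 under independence, were weighed as 1 pattern. A shared estimate of the spread was argued against by fits of each organ alone on its own 4 arrays, which gave 158 same-direction calls against 19.6 under independence. Sequence variants within the 200 tested genes nearest to Hr39 were argued against as the whole cause. Of the 158 genes, 5.06% (8, 95% Clopper-Pearson interval 2.21% to 9.73%) lay among those 200. Still, 4% of those 200 were called against 1.97% of the rest (Fisher's exact test, two-sided p = 0.0653). Genes farther along the same chromosome were not counted, so variants carried along over a longer stretch remain open. Variants under single probe sets cannot be told apart, since 44% of 25 further probe sets of these genes moved the same way in both organs (11, interval 24.4% to 65.1%). A strain difference between the mutant and wild-type flies and an effect of Hr39 in both organs may each account for the pattern, and neither was tested.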

How the results depend on the processing

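The alternatives named as chosen after seeing the data include those for the changes shared by both organs, the removal of near-saturated probe sets and camera with a variance trend. The list tests use their own variance, so no value exists for them with no variance trend or a robust variance. Signal over background limits the dim probe sets, and the brightest probe sets lie near the top of the scale. Of 240 called values of named genes, 179 kept their call under every alternative fixed for single genes, although 27 of the 240, and 9 of the 179, gave no value under the stricter filter. Of the 240, 209 differed at least 2-fold and 197 had an adjusted p below 0.01, thresholds tried on single genes only after seeing the data, and 175 of the 179 met both. Over 4288 values 3951 kept direction and call, 336 kept direction without the call and 1 turned: Hsc70-4 between wild-type organs was -0.0648 with quantile normalization.

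The fall of Hr39 in the spermathecae (1630002_s_at) lost its call at -0.726 with quantile normalization, at -0.734 with median centring, and at -0.726 with no filter and with no variance trend, where more tests or another spread end the call at the same size. In the lower tract 1628556_s_at was 0.101 with quantile normalization, and 1632845_at passed at -1.14 with no variance trend (adjusted p = 0.0207). The cause was not tested. The percent of spermatheca-enriched probe sets that were lower and higher was 5.32 and 3.36 with median centring, 5.49 and 3.1 with no filter, 5.36 and 2.76 with no variance trend and 4.17 and 2.54 at an adjusted p below 0.01. The lower percent was 7.89 with a pseudocount of 20, and the higher percent 5.52 with the stricter filter. The cause was not tested. By construction, a 2-fold minimum left fewer calls: 529 in mutant spermathecae, 2818 between wild-type organs (39.7% higher in spermathecae), 3003 between mutant organs and 128 shared by both organs. So did an adjusted p below 0.01, with 357 in mutant spermathecae, 274 in the mutant lower tract, 121 for the interaction and 83 shared by both organs. The number of lists passing was 0 in each comparison with an estimated correlation. With fry it was 6 in mutant spermathecae, 4 in the mutant lower tract, 18 between wild-type organs and 1 for the interaction. In the mutant lower tract it was 4 with no filter and 1 without near-saturated probe sets, and in mutant spermathecae 3 without near-saturated probe sets. The cause was not tested.

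Leaving out each array in turn leaves a group with 1 array, assumed to vary like the others. The ranges were 313 to 1132 called in mutant spermathecae, 178 to 713 in the mutant lower tract, 3606 to 4164 between wild-type organs, 3183 to 4948 between mutant organs, 116 to 440 for the interaction and 82 to 227 shared by both organs. Lists passing ranged from 0 to 3, 1 to 5, 11 to 12 and 1 to 6 in mutant spermathecae, mutant lower tract, wild-type organs and interaction. The enriched percent lower ranged from 3.36 to 9.33 and higher from 1.46 to 5.39. Organ differences kept in the mutant ranged from 63.2% to 81.8%. The Hr39 effect in spermathecae and lower tract ranged from -0.815 to -0.638 and -0.472 to -0.218 (1630002_s_at), from -0.639 to -0.5 and -0.676 to -0.524 (1631402_s_at), from -0.722 to -0.522 and -1.28 to -1 (1632845_at), and from -0.348 to 0.246 and -0.185 to 0.0869 (1628556_s_at). The last turned to 0.147 without mutant spermathecae replicate 1 and to 0.073 without wild-type lower tract replicate 1. Effects on ftz-f1, none called, ranged in spermathecae from -0.496 to 0.124 (1624520_a_at) and from -0.274 to 0.423 (1640821_at), and in the lower tract from -0.358 to 0.0183 and from -0.368 to 1.03, with -0.0207 for the latter without mutant lower tract replicate 2. Between wild-type organs 1624520_a_at ranged from -0.554 to 0.0657. Arrays with the same replicate number showed no shared deviation across all probe sets (correlations between -0.0323 and 0.026). The labels do not say whether they were processed together, and a deviation shared by fewer probe sets is not excluded. A replicate block gave 775 and 569 calls in mutant spermathecae and lower tract, 294 for the interaction and 190 shared by both organs.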

Other observations

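The tests of signal saturation, transcripts independent of Hr39, germline material and array noise were chosen only after the results were seen.

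Single transcription factor genes differed between the wild-type organs, and neither of their lists passed camera. The nuclear receptor genes kni, eg and knrl were lower in spermathecae by log2 differences of -5.59, -5.21 and -4.96 (SE 0.301, 0.355 and 0.412, n = 2 per group), while Hr39 was higher at 3.20. In the nuclear receptor list 8 of 17 probe sets were higher and 6 lower (8 and 6 adjusted over the list alone), with a median of 0.67 and a mean of -0.33 (camera up, adjusted p = 0.719). Among tract patterning factors 7 of 18 were higher and 8 lower (7 and 8 adjusted over the list alone), with the zinc finger gene peb at 5.34 and the Runx gene lz at 3.53, and the homeobox genes en and ems at -4.82 and -3.95. In the organ with less signal kni, eg, knrl, en, ems and lz were below the array medians, so these sizes depend on the pseudocount.

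Single members of further lists differed between the wild-type organs. Glycan and mucin genes were higher in spermathecae for 10 of 21 and lower for 4 (10 and 4 adjusted over the list alone), with Papss at 4.71. Glutathione S-transferases were higher for 10 of 29 and lower for 5 (11 and 5 adjusted over the list alone), with GstS1 at 2.31. Heat shock proteins were higher for 4 of 6 (4 adjusted over the list alone), with Hsp27 at 2.22. Serpins were lower for 7 of 18 and higher for 3 (8 and 3 adjusted over the list alone), with Spn47C at -4.18, antioxidant enzymes lower for 6 of 18 and higher for 4 (8 and 4 adjusted over the list alone), with Cat (catalase) at 1.45, and none of these lists passed camera. Germline genes were lower for 6 of 13 and higher for 3 (6 and 3 adjusted over the list alone), with grk at -2.94, and the lower tract array with germline transcripts enters that comparison. For grk that array did not add to the difference, since it read 446.1 there against 563.2 on wild-type lower tract replicate 2. Synapsin (Syn) was higher at 4.49 among neuronal genes, of which 7 of 12 were lower and 2 higher (7 and 3 adjusted over the list alone).

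Bright spermathecal proteases showed no called mutant difference in spermathecae, and 2 explanations were weighed. Saturation predicts that their signal follows the spike-in ceiling, and the median gap between their log2 ratios and those of the brightest spike-in was 0.0797, against 0.34 for 396 mid-signal probe sets. The ceiling may therefore hide a difference, also in a fit of the 4 spermatheca arrays alone (median SE 0.262). Transcripts that do not depend on Hr39 would give the same median of -0.00179, so the 2 explanations cannot be told apart where the signal is near the ceiling.

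Germline transcripts on wild-type lower tract replicate 1 were weighed in the same way. The germline list was higher than on replicate 2 by a median log2 of 2.07, with 10 of 13 members higher, while muscle genes differed by -0.175. Array noise was argued against, since 0% of 10000 random lists of like expression had an excess as large (upper end of their 95% range 0.398). Germline material in that sample, such as ovary or eggs left in the tract, is a candidate explanation, with osk at 555.6, CycB at 1134 and exu at 339.5 against 20.8, 88.2 and 15.2. Eggshell genes reached 115.8 at most, with a median of 11.1 against 6.05, and the arrays of a group differ in no factor that the labels name.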
